A study of Mus musculus with 4 samples.

How the data were processed

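The data are single-cell RNA profiles of the longitudinal muscle and myenteric plexus of the small bowel of 4 wild-type mice, 2 males and 2 females aged 70 days. Per the labels' protocols, the tissue was digested for 35 min at 37 °C with 2 µM actinomycin D, passed through sieves of 100 and 40 µm, and made into 10x Genomics 3′ libraries for a target of 20000 reads per cell. The deposited files hold raw UMI counts per gene and barcode, 1 table per mouse with 32285 genes named by symbol, and every value is a whole number. FastQC, Cell Ranger 7.0, Seurat 5.0 and the genome build GRCm38 are named per the submitters' processing notes. What each tool did, the aligner's settings, the annotation release and the rule that left these barcodes are not given in the sources used here. Each barcode deposited by the authors had at least 500 UMI counts. The deposited counts per mouse had median depths of 4745 UMIs (male replicate 1), 4688.5 (male replicate 2), 4927 (female replicate 1) and 5325 (female replicate 2), where replicate numbers follow the order of the samples and pair nothing.

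Cells with at least 300 genes, at least 500 UMIs and at most 20% mitochondrial UMIs were kept, which left 35422 cells. Doublets were scored per mouse with Scrublet in scanpy 1.11.5, and the cells with the highest scores were removed at 0.8% per 1000 cells, which took out 238 and 840 cells from the male replicates 1 and 2 and 669 and 895 from the female replicates 1 and 2, or 4.37%, 8.20%, 7.32% and 8.46%. The remaining 32780 cells were scaled to 10000 counts, logged, and clustered on 3000 variable genes with 40 principal components, 20 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9), without correction between mice. Genes of 5 lists (chemokine ligands, chemokine receptors, macrophage growth and neuroimmune signals, neurotrophic factors and receptors, and a mesoderm-derived enteric neuron list) and the sex-linked genes were left out of clustering and naming, 118 list genes of which 100 were measured well enough to test. This gave 38 clusters.

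Names came from 259 marker genes of 21 cell types that, with the tests, the gene lists and most alternatives, were fixed before the data were examined. A cluster took the name of the type with the highest mean z score of its markers if that score was at least 1. At least 3 markers also had to be detected at 10 CPM or more with a log2 fold of at least 1. Its 10 leading genes by fold had to hold more markers of that type than of any other, or no marker of any type. A cluster with no marker of any type there and a median depth far below that of its mice stayed unnamed. This scoring rule was set after the clusters were first seen. An unnamed cluster of at least 250 cells from at least 3 mice was clustered again, which split 1 cluster of myeloid cells and gave 46 clusters, of which 36 took 16 names and 10 stayed unnamed. Cluster 21, called macrophage-like, was led by proliferation genes (Top2a, Mki67), cluster 11, also macrophage-like, by the pancreatic gene Ctrb1 beside C1qa and C1qb, cluster 2 by MHC class II genes beside C1qa, and the monocyte-like cluster 42 by Prg4, Chil3, Alox15 and Arg1. The interstitial cell of Cajal-like cluster 23 (310 cells) and the smooth muscle-like cluster 14 (753 cells) had 0 markers of their type among their 10 leading genes. Names rebuilt this way can differ from those of the study. A class was tested if each mouse had at least 10 cells of it, which held for 13 classes.

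UMI counts were summed per mouse and class, and the mouse was the unit of replication. Sums were tested with edgeR 4.0.16 (quasi-likelihood test, TMM normalization, its default filter on low counts) and limma 3.58.1 in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Class comparisons used 1 fit over the 13 classes with the mouse as a block. Each of 7 classes was set against the unweighted mean of the other classes, taken on the log scale. Only list genes with a log2 difference above 1 or below -1 were counted. Monocyte-like and macrophage-like cells were compared in the same fit without the limit on the difference. Males and females were compared per class and for all cells summed, and the difference of a class contrast between the sexes was tested as an interaction. Shares of cells were compared by exact permutation of 2 against 2 mice, whose smallest two-sided p is 0.333. Cells with transcripts of the 16 enteric neuron markers or of the 13 mesoderm-derived list genes were counted after thinning each cell to 1000 UMIs, as differences from vascular endothelial-like cells of the same mouse, by an exact sign-flip test over 4 mice with a smallest two-sided p of 0.125. CPM are the counts divided by all UMIs of the sum. Gene positions were matched by symbol to GENCODE vM21 on GRCm38, which found 31424 of the 32285 symbols, with starts counted from 1.

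Genes named in the text followed a rule. All 10 sex-linked genes were named, then, for the all-cell sum and at most 4 classes with most calls, up to 4 higher and 4 lower genes whose male and female values did not overlap. For the classes, 15 genes were always named (Ccl2, Ccr2, Cx3cr1, Cx3cl1, Csf1, Il34, Csf2rb, Calcb, Met, Cdh3, Slpi, Ntf3, Gdnf, Ret and Bmp2), then the 4 with the largest log2 difference per list and class among those with at least 20 counts in each mouse, and for list tests up to 4 members with the largest difference. The monocyte against macrophage comparison names further list genes by size after their values were seen. A few listed genes are not reported here, in the text or in the plot of that comparison. Near-identical copies such as Hba-a1 and Hba-a2 or the Ccl27a family can share reads, so their values are uncertain.

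Lists were tested between the sexes with camera at a preset correlation of 0.01 and with an estimated one, 142 tests of 12 lists over the classes. The numbers of tests called at the preset correlation, lower and higher in males, were 8 and 1 for MHC class II, 6 and 1 for cell cycle, 6 and 0 for interferon response, 5 and 0 for immediate early and heat shock genes, 4 and 1 for chemokine ligands, 4 and 0 for chemokine receptors, 4 and 0 for extracellular matrix, 3 and 0 for contractile genes, 0 and 4 for the mesoderm-derived enteric neuron list, 0 and 2 for mitochondrial genes, 0 and 1 for macrophage growth and neuroimmune signals, and 0 and 0 for neurotrophic factors and receptors. With the estimated correlation 0 of the 142 tests passed. A list of 23 pancreatic acinar genes was written after a cluster led by such genes was seen.

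The edgeR fits of 4 comparisons were checked on simulated data with 200 changed genes and an inverse dispersion of 20, and thinning was checked separately. The monocyte-like against macrophage-like comparison, the other classes, the interactions and the list tests were not simulated. For the sexes in all cells (18942 genes) it recovered 1.49%, 19.4% and 98.5% of genes changed 1.5-, 2- and 4-fold, in macrophage-like cells (13938 genes) 2.99%, 17.9% and 97.0%, and in enteric neuron-like cells (9095 genes) 2.99%, 5.97% and 57.6%. For macrophage-like against the other classes (13709 genes) it recovered 37.3%, 98.5% and 100%. False calls were 4 of 83, 4 of 82, 3 of 47 and 12 of 169 calls in these 4 comparisons, so in the last 2 their share was above the threshold of 0.05. The alternatives were DESeq2 1.42.0, edgeR with RLE size factors, no filter on low counts, a stricter cell filter (500 genes, 1000 UMIs, 10% mitochondrial UMIs), doublets kept, Leiden resolution 2.0 (54 clusters), each mouse left out, no replicate block, fibroblast-like cells as background, thinning to 2000 UMIs and the estimated correlation. With 1 mouse left out, the lone sample of its sex is assumed to vary like the others. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0 and matplotlib 3.10.9.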

Results

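Droplet-based 3′ single-cell RNA sequencing (10x Genomics) was run on the longitudinal muscle and myenteric plexus of the small bowel, the outer layer of the gut wall that holds much of the enteric nervous system. The tissue came from 4 wild-type mice aged 70 days, 2 males and 2 females, that shared a date of birth and a day of experiment. The deposited UMI counts held 5775 barcodes and 49490998 UMIs for male replicate 1, 11108 barcodes and 75278438 UMIs for male replicate 2, 9685 barcodes and 66398062 UMIs for female replicate 1, and 11638 barcodes and 79339533 UMIs for female replicate 2. After filtering and removal of likely doublets, 32780 cells remained: 5212 and 9409 from the male replicates 1 and 2, and 8476 and 9683 from the female replicates 1 and 2. The labels give no disease or treatment group, so the comparisons were between cell classes within the mice and between the sexes. Class values are CPM, a gene's UMIs summed per mouse and class and scaled to a common total. They are means over 4 mice, given with ± SD in many but not all places. Log2 differences carry a standard error from edgeR's fit. It draws on the variation between the mouse sums, with information shared across genes, and is not an SD over mice.

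Macrophage-like cells were the most abundant class in the muscle layer, at 35.3% ± 5.43 of kept cells (SD, n = 4 mice, 11478 cells). Fibroblast-like cells made up 15.8% ± 5.87, enteric glia-like cells 14.4% ± 4.85, mesothelial-like cells 8.14% ± 6.03 and vascular endothelial-like cells 7.38% ± 1.36. Smooth muscle-like cells held 4.83% ± 2.95 and interstitial cell of Cajal-like cells, named after the pacemaker cells of the gut, 3.58% ± 1.97. Enteric neuron-like cells were rare, at 1.11% ± 0.701 (321 cells), as were monocyte-like cells, at 0.797% ± 0.596 (273 cells). T cell-like cells held 2.07% ± 1.31, dendritic cell-like cells 0.598% ± 0.420, pericyte-like cells 0.823% ± 0.284 and lymphatic endothelial-like cells 0.591% ± 0.482. A further 4.25% ± 2.88 of cells lay in 10 clusters that stayed unnamed. Erythrocyte-, neutrophil- and epithelial-like cells were too few in some mice to be tested.

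Mesothelial-like cells averaged 12.1% of cells in males and 4.19% in females, and enteric glia-like cells 17.6% and 11.2%. T cell-like cells averaged 0.979% in males and 3.15% in females, and dendritic cell-like cells 0.339% and 0.858%. These 4 differences had the smallest p that 2 mice against 2 can give, 0.333 (exact permutation test, two-sided), so none could pass 0.05. Macrophage-like cells averaged 32.3% in males and 38.3% in females (exact permutation p 0.667), and the monocyte-like share differed with an exact permutation p of 0.667 as well. Shares depend on the dissociation and on the cell filter, and 2 clusters that came almost wholly from female replicate 1 held 54.1% of its macrophage-like cells.

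**Figure D1:**
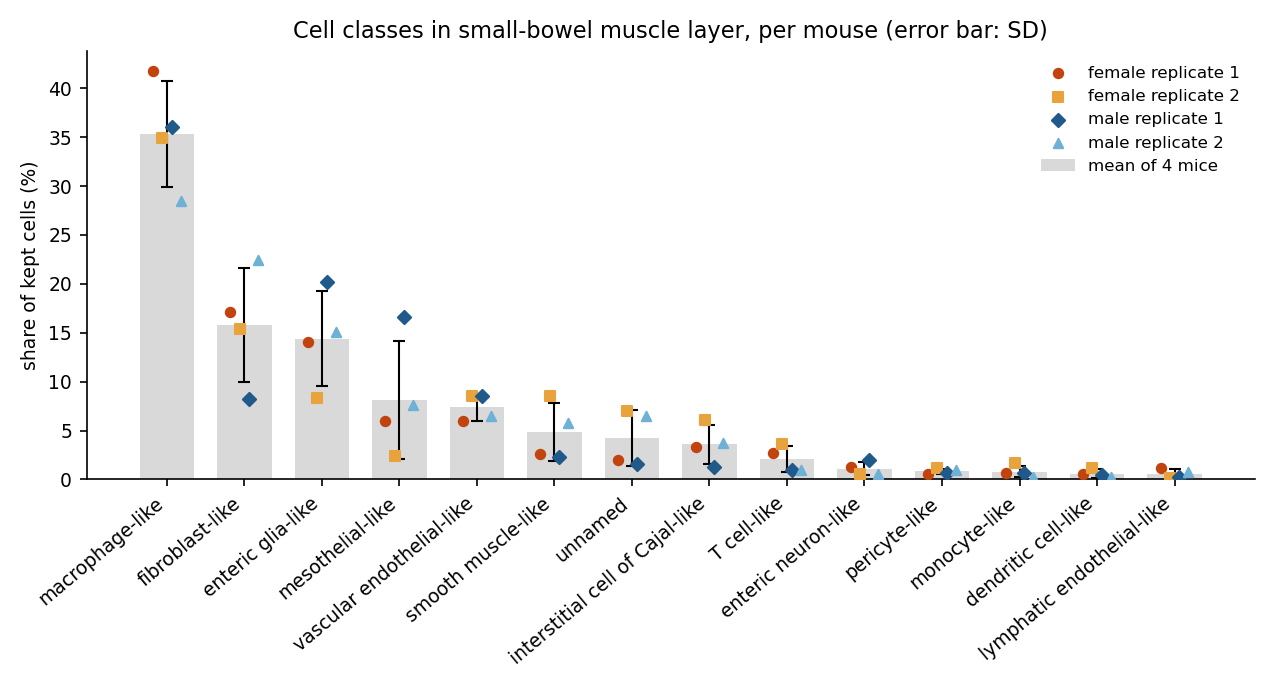
Share of kept cells (%) in each cell class, with bars for the mean of 4 mice, error bars for the SD and points for the mice. Macrophage-like cells lead at 35.3%, and monocyte-like and enteric neuron-like cells average 0.797% and 1.11%.

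The next comparison asked which chemokines, growth factors and neurotrophic signals each class expressed, since the series title concerns monocyte recruitment and remodelling of the enteric nervous system. It covered 100 measured genes of 5 lists that were kept out of the clustering. Genes in 2 lists are counted in both. Macrophage-like cells had 42 of these genes higher than the log-scale mean of the other classes (42 adjusted over the list alone) and 12 lower. Classes with few counts of a gene pull that mean down. A gene can thus be called higher in a class while another class holds more of it. Of 25 chemokine ligands 18 were higher, 1 was lower and 6 did not pass. Ccl8 was higher by 7.52 ± 0.22 on the log2 scale (1531 ± 858 CPM), Ccl12 by 6.69 ± 0.24 (970 ± 395 CPM), Ccl7 by 6.60 ± 0.18 (192 ± 95.4 CPM) and Ccl24, an eosinophil attractant, by 6.20 ± 0.28 (40.3 ± 16.4 CPM). Ccl7, Ccl8 and Ccl12 lie with Ccl2 in a cluster on chromosome 11 and encode ligands that attract monocytes. Of 16 chemokine receptors 7 were higher and 2 lower, led by the fractalkine receptor Cx3cr1 (6.05 ± 0.16, 933 ± 93.2 CPM), Ccr1 (159 ± 13.3 CPM) and Ccr2 (4.57 ± 0.22, 255 ± 27.7 CPM). Among 27 macrophage growth and neuroimmune genes 14 were higher and 4 lower, and the higher ones included Trem2 (166 CPM), Csf2rb (50.1 CPM), Il1b (23.1 CPM) and Tnf (log2 difference 5.79). Bmp2, a macrophage signal to enteric neurons, was higher by 4.29 ± 0.27 at 34.8 ± 5.87 CPM. Of 23 neurotrophic genes 3 were higher (Igf1, Hgf and Kitl) and 3 lower, and Igf1 reached 313 ± 157 CPM. In the mesoderm-derived enteric neuron list, 12 measured genes taken from knowledge of proposed markers of such neurons, 1 was higher in macrophage-like cells, Il18 by 3.31 ± 0.14, and 2 were lower.

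Monocyte-like cells had 40 list genes higher (40 adjusted over the list alone) and 15 lower. They were marked by Ccr2, the receptor that draws monocytes to Ccl2, at 986 ± 47.0 CPM. This was 6.57 ± 0.23 above the log-scale mean of the other classes. Among chemokine ligands 16 were higher and 2 lower, led by Ccl9 (7.10 ± 0.18, 510 ± 269 CPM) and Ccl6 (6.92 ± 0.21, 1453 ± 711 CPM). Pf4 was at 691 ± 421 CPM and Cxcl16 at 207 ± 25.4 CPM. Of the receptors 8 were higher and 0 lower, including Ccr1 and Cx3cr1 (455 ± 48.4 CPM). Of the growth and neuroimmune genes 11 were higher and 6 lower, with Csf2rb at 101 ± 18.5 CPM and Trem2 at 194 ± 108 CPM. Of the neurotrophic genes 4 were higher and 5 lower, and of the mesoderm-derived list 3 were higher and 2 lower.

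Mesothelial-like cells, the serosal lining, had 34 list genes higher (34 adjusted over the list alone) and 21 lower. They held 11 of the 12 mesoderm-derived list genes above the log-scale mean of the other classes. Slpi, a secreted protease inhibitor, reached 18836 ± 4993 CPM (9.72 ± 0.19), Fmo2 4806 ± 393 CPM (8.44 ± 0.13), Clic3 174 ± 42.4 CPM (11.07 ± 0.18) and the cadherin Cdh3 162 ± 17.5 CPM (7.66 ± 0.15). The exception was Nos1, the nitric oxide synthase of inhibitory enteric neurons, which was lower by a log2 difference of -3.06 ± 0.57. Of the neurotrophic genes 7 were higher and 5 lower. They included Ntf3, the ligand of TrkC, at 114 ± 29.0 CPM (7.49 ± 0.22), Met, the receptor of hepatocyte growth factor, at 58.0 ± 5.38 CPM (5.07 ± 0.17), Ntf5 at 18.5 CPM and Bdnf. Of the growth and neuroimmune genes 14 were higher and 2 lower, with Gas6 at 1367 ± 95.5 CPM, Il18 at 208 ± 11.6 CPM, Bmp6 at 92.9 CPM and the alarmin Il33 at 85.0 CPM. Only 3 ligands (Cxcl10, Ccl27a and Cxcl16) and 2 receptors (Ackr3 at 121 CPM and Ackr4) were higher, against 9 and 4 lower.

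Enteric neuron-like cells had 24 list genes higher (22 adjusted over the list alone) and 11 lower. Nos1 was higher by 8.90 ± 0.12 (867 ± 143 CPM) and the neuropeptide gene Calcb by 8.87 ± 0.20 (458 ± 234 CPM), and 4 of the mesoderm-derived list were higher and 3 lower. Ret, the GDNF-family receptor needed for enteric neurons, was higher by 8.48 ± 0.20 (192 CPM), beside Ngfr (197 CPM), Gfra1 (189 CPM) and Nrg1 (157 CPM). Of the neurotrophic genes 12 were higher and 2 lower, of the growth and neuroimmune genes 6 and 2, of the ligands 2 and 3, and of the receptors 1 and 1. Cd200, an inhibitor of myeloid cells, was at 188 CPM.

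Enteric glia-like cells had 29 list genes higher (28 adjusted over the list alone) and 16 lower. Ccl2, the main attractant of Ccr2-bearing monocytes, was higher by 2.94 ± 0.29 at 65.3 ± 11.9 CPM, and Il34, a ligand of the macrophage receptor Csf1r, by 5.10 ± 0.27 at 39.5 ± 15.6 CPM. Of the ligands 6 were higher and 4 lower, and of the receptors 2 were higher (Ackr1 and Ccrl2) and 5 lower. Of the neurotrophic genes 11 were higher and 4 lower, with Gfra1 at 729 ± 35.6 CPM (7.03 ± 0.12), Gfra2 at 409 CPM, Ngfr at 130 CPM and Gfra3 at 52.4 CPM. Of the growth and neuroimmune genes 8 were higher and 2 lower, with Tgfb2 at 717 ± 71.0 CPM (4.52 ± 0.15), and of the mesoderm-derived list 3 and 1.

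Fibroblast-like cells had 39 list genes higher (39 adjusted over the list alone) and 14 lower. Cxcl12, the Cxcr4 ligand, was at 445 ± 127 CPM (4.74 ± 0.13), the scavenging receptor Ackr4 at 299 CPM, Ntrk3 at 160 CPM and Bmp2 at 112 ± 23.6 CPM (5.72 ± 0.23). Of the neurotrophic genes 14 were higher and 1 lower, of the growth and neuroimmune genes 13 and 2, of the ligands 6 and 6, of the receptors 4 and 4, and of the mesoderm-derived list 3 and 2. Ccl2 was higher by 1.05 ± 0.34 at 18.9 CPM, a call that DESeq2 did not make (log2 difference 0.89). Smooth muscle-like cells had 20 higher (20 adjusted over the list alone) and 23 lower, and the higher ones included the neurturin gene Nrtn (4.63 ± 0.14, 112 ± 27.4 CPM), Cdh3 (4.82 ± 0.25, 23.8 CPM), Cxcl14 (23.6 CPM) and Bmpr1a (207 CPM). Of the neurotrophic genes 7 were higher and 2 lower in smooth muscle-like cells, of the growth and neuroimmune genes 5 and 6, of the ligands 4 and 8, of the receptors 1 and 5, and of the mesoderm-derived list 3 and 3. Free RNA from abundant classes adds UMIs to all classes, so low CPM were not read as expression. The counts of lower genes depended on the test, since DESeq2 called 36 genes lower in macrophage-like cells, 46 in mesothelial-like, 36 in enteric glia-like, 32 in fibroblast-like, 25 in monocyte-like and 49 in smooth muscle-like cells.

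Signals between monocytes, macrophages and the plexus were spread over several classes. Ccl2 (chromosome 11, 82035571 to 82037453, build GRCm38) was highest in macrophage-like cells at 141 ± 55.7 CPM, then in monocyte-like cells at 123 ± 75.2 CPM and in enteric glia-like cells. Ccr2 (chromosome 9, 124101950 to 124113557) was highest in monocyte-like cells, then in dendritic cell-like cells at 476 ± 118 CPM and T cell-like cells at 328 ± 43.6 CPM. Csf1 (chromosome 3, 107741048 to 107760469), the growth factor that macrophages need, was highest in mesothelial-like cells at 196 ± 13.2 CPM (3.57 ± 0.11), then in interstitial cell of Cajal-like cells at 61.8 ± 32.8 CPM and fibroblast-like cells at 61.8 ± 8.77 CPM, and it was lower in macrophage-like cells by a log2 difference of -1.76 ± 0.21. Il34 (chromosome 8, 110741829 to 110805924), the other Csf1r ligand, was highest in pericyte-like cells at 410 ± 51.0 CPM (8.47 ± 0.32). The fractalkine gene Cx3cl1 was at 25.9 ± 1.38 CPM in interstitial cell of Cajal-like and 25.1 ± 4.23 CPM in vascular endothelial-like cells. Gdnf, the Ret ligand, was highest in interstitial cell of Cajal-like cells at 17.9 ± 3.86 CPM, against 2.18 CPM in fibroblast-like cells. Ntf3 was at 48.4 ± 17.4 CPM in vascular endothelial-like cells and Met at 48.8 ± 27.0 CPM in lymphatic endothelial-like cells, and Bmp2 was at 60.2 ± 17.8 CPM in pericyte-like cells.

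**Figure D2:**
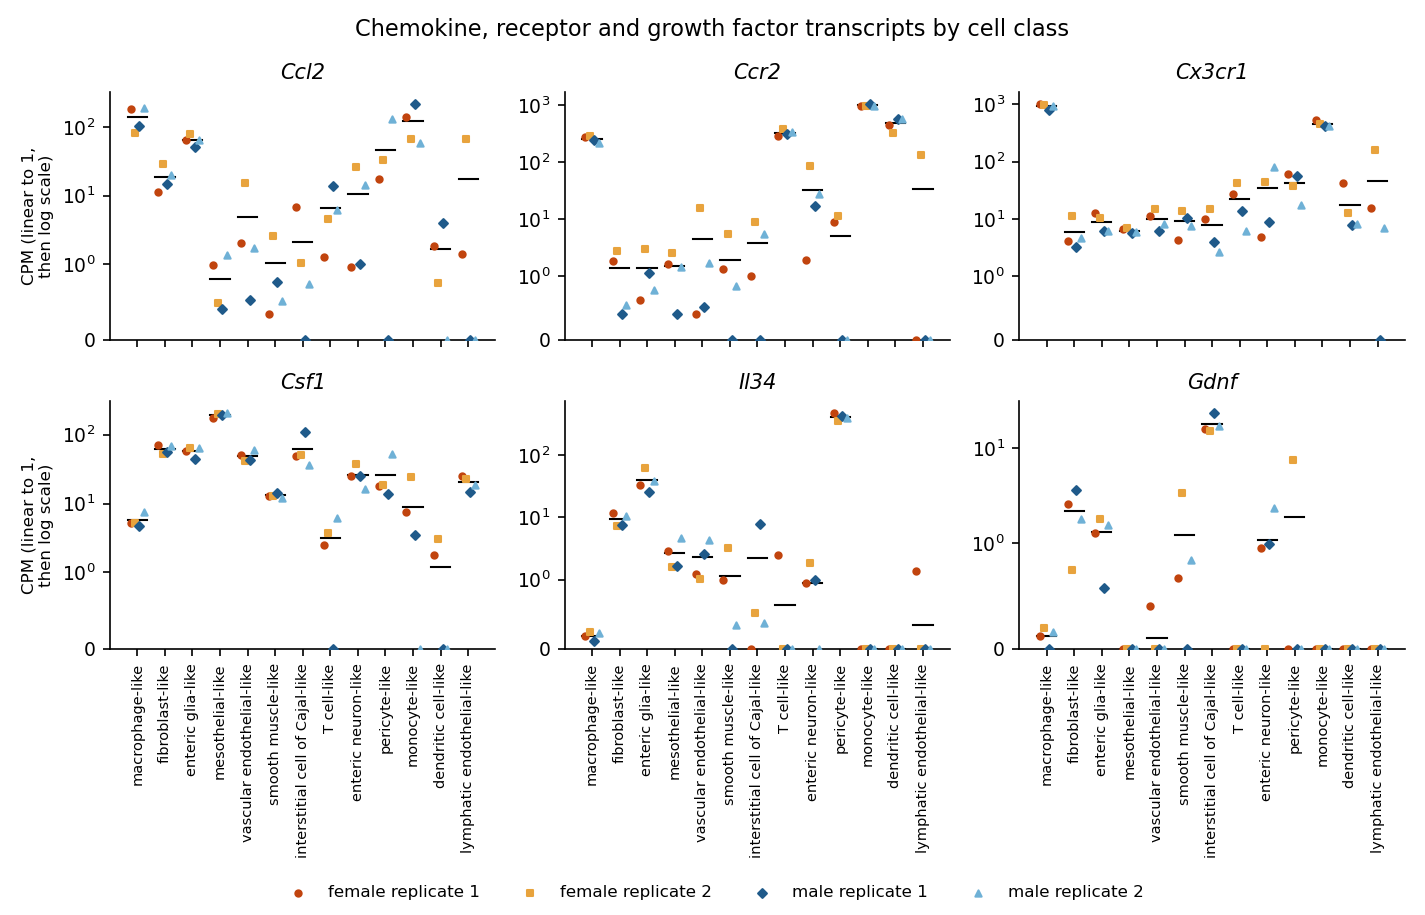
CPM of Ccl2, Ccr2, Cx3cr1, Csf1, Il34 and Gdnf per cell class, on an axis that is linear up to 1 and logarithmic above, with a point per mouse and a line at the mean of 4 mice. Ccr2 is highest in monocyte-like cells (986 CPM), Cx3cr1 in macrophage-like cells (933 CPM), Csf1 in mesothelial-like cells (196 CPM) and Il34 in pericyte-like cells (410 CPM).

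**Figure D3:**
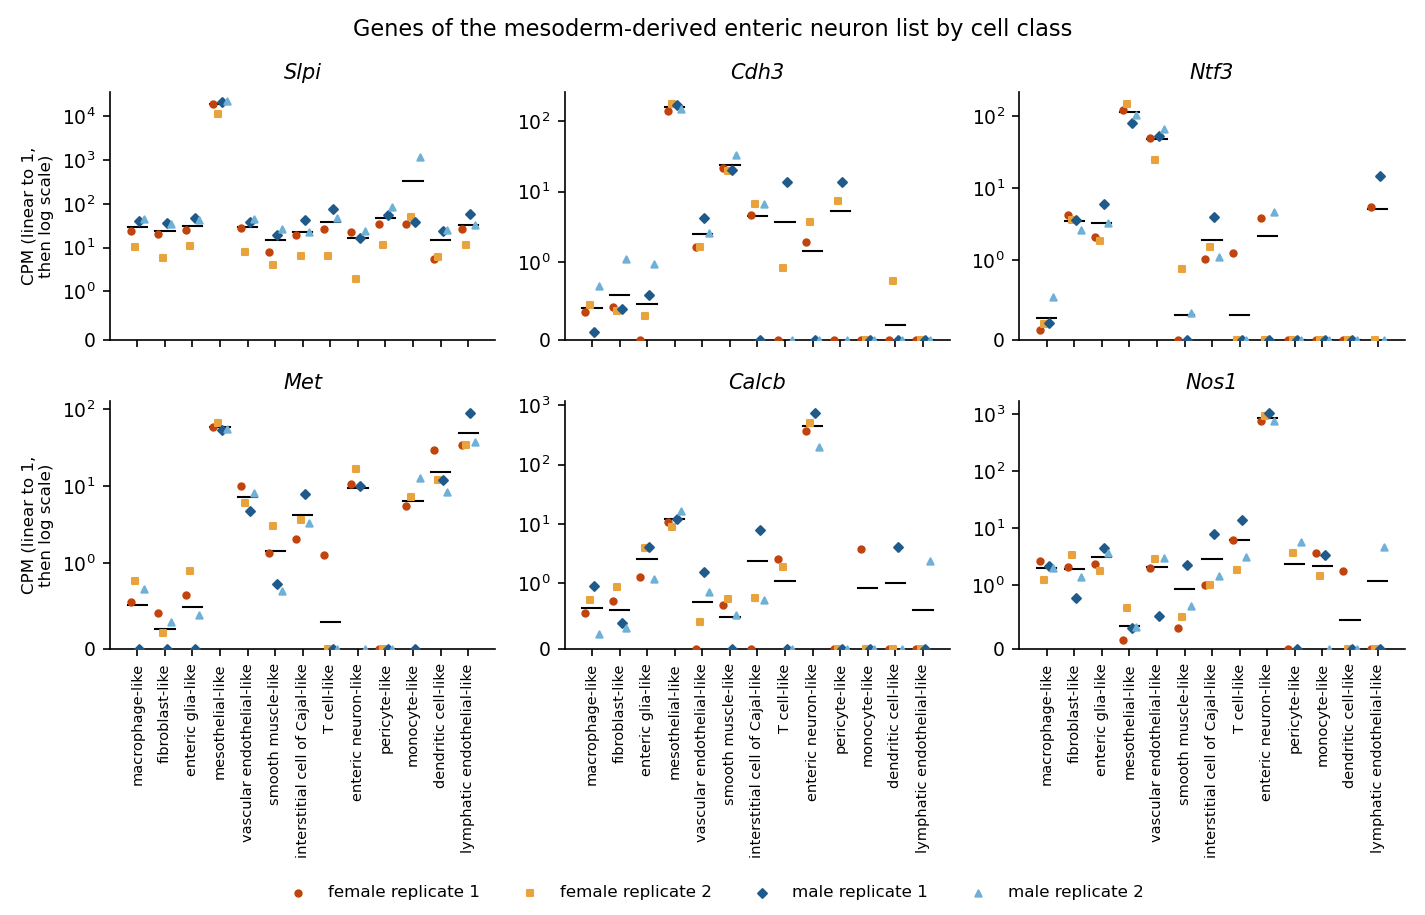
CPM of Slpi, Cdh3, Ntf3, Met, Calcb and Nos1, all from the mesoderm-derived enteric neuron list, per cell class, on an axis that is linear up to 1 and logarithmic above, with a point per mouse and a line at the mean of 4 mice. Slpi, Cdh3, Ntf3 and Met are highest in mesothelial-like cells (18836, 162, 114 and 58.0 CPM), and Calcb and Nos1 in enteric neuron-like cells (458 and 867 CPM).

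Monocyte-like and macrophage-like cells were then compared directly, a question raised by the title's monocyte recruitment. Monocyte-like cells held more Ccr2 (log2 difference 1.84 ± 0.34, edgeR adjusted p 2.74e-05), Ccl9 (1.93 ± 0.22), Ccl6 (1.53) and Spp1 (5.62 ± 0.52). They held less Cx3cr1 (-1.17 ± 0.29), Ccl8 (-4.26 ± 0.46), Ccl12 (-3.28 ± 0.49), Ccl7 (-2.80 ± 0.34), Bmp2 (-4.01 ± 0.67) and Gas6, a bridge for the uptake of dead cells (-3.56 ± 0.27). In all, 36 list genes differed by edgeR's test (37 adjusted over the list alone), 15 higher and 21 lower in monocyte-like cells. The other lower genes included Bmpr1a (-3.37 ± 0.40), Kitl (-2.56), Igf1 (-2.11) and Pf4 (-1.66). Cx3cl1 had 0 counts in monocyte-like cells of the 4 mice, against 2.58 CPM in macrophage-like cells, at least 2.11-fold lower against a floor of 3 counts over the mice. The other higher genes included Met (3.33 ± 0.66), Ccl5 (1.90), Il1b (1.37) and Mif (1.31).

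Single mice or clusters set 5 of the higher values. Ccr7 (5.65 ± 1.01) turned to -1.61 without female replicate 1, and Cxcl9 (2.29) to -0.073 and Csf1 (1.31) to -0.44 without female replicate 2. Slpi (2.79 ± 0.41), at 324 ± 566 CPM in monocyte-like cells, lost its call and Ccl24 (1.29) turned to -0.26 when a monocyte-like cluster with fewer than 3 marker genes among its leading genes, led by Prg4, Chil3, Alox15 and Arg1, was left out.

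**Figure D4:**
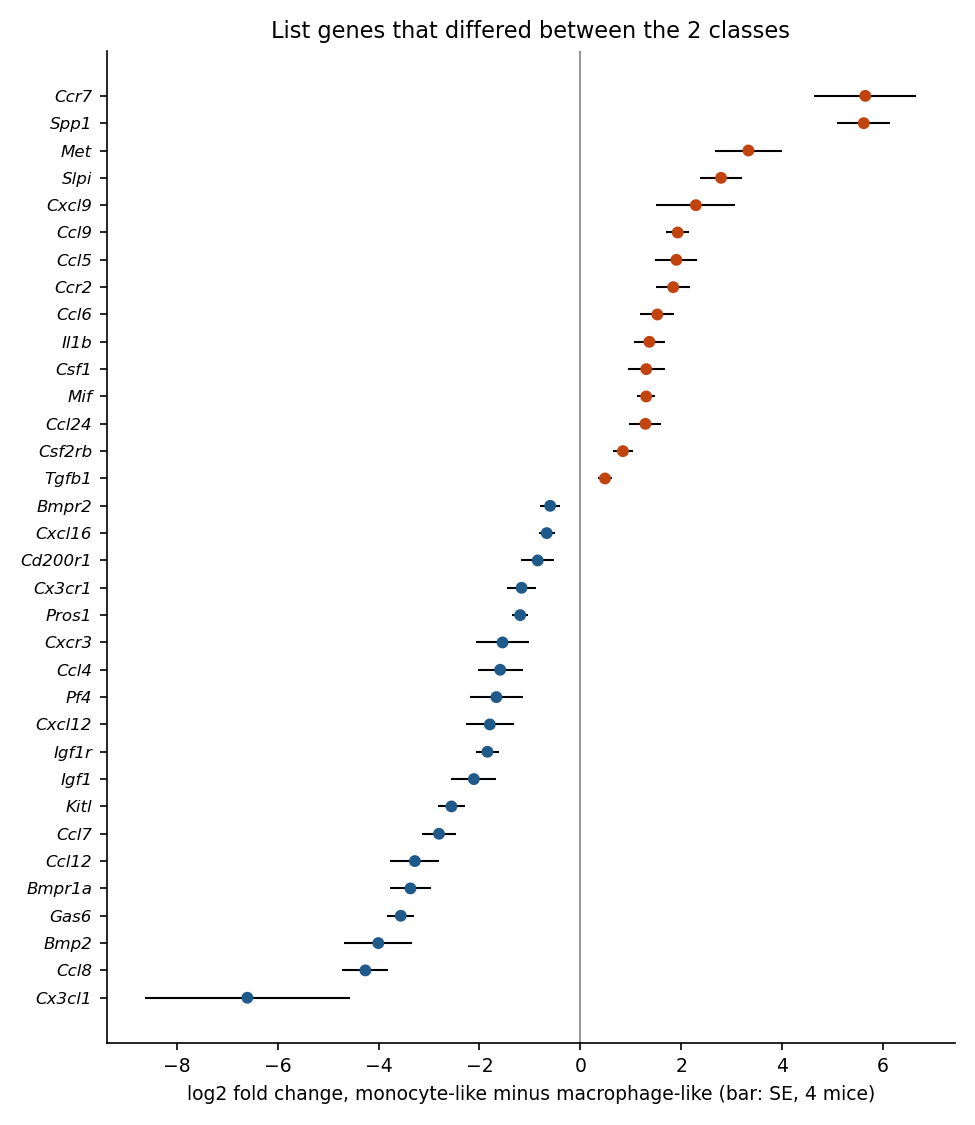
Log2 difference, monocyte-like minus macrophage-like, of 34 of the 36 list genes that passed, with error bars for the standard error over 4 mice. Ccr7 and Spp1 lie highest at 5.65 and 5.62, Ccl8 lies at -4.26, and the value of Cx3cl1 is a fitted one from 0 counts in monocyte-like cells and is no bound.

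The next comparison asked whether macrophage- or monocyte-like cells carried transcripts of enteric neurons. Each cell was thinned to 1000 UMIs, and vascular endothelial-like cells gave the background. At least 1 UMI of 16 enteric neuron markers appeared in 15.1% ± 0.952 of macrophage-like and 7.29% ± 1.51 of monocyte-like cells, below the 21.0% ± 2.96 of vascular endothelial-like cells. The differences were -5.95 ± 2.73 and -13.7 percentage points, with 0 of 4 mice above background for macrophage-like cells (the smallest p that an exact two-sided sign-flip permutation over 4 mice allows, which is above 0.05). In enteric neuron-like cells the share was 96.2%. The background class itself held Stmn2 in 13.3% of cells, and against fibroblast-like cells (4.54%) the macrophage-like and monocyte-like differences turned to 10.5 and 2.75 percentage points, with Rtn1 in 11.7% of macrophage-like cells. At 2000 UMIs the macrophage-like difference was -9.46 ± 6.44 percentage points with 1 of 4 mice above background, and the monocyte-like one had 0 of 4. Without thinning the macrophage-like share was 45.2% and the monocyte-like share 36.1%, against 48.0% in vascular endothelial-like cells, with 1 of 4 mice above background in each.

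UMIs of the mesoderm-derived list appeared in 9.29% ± 2.03 of macrophage-like and 6.30% ± 3.51 of monocyte-like cells, against 42.0% ± 11.1 of vascular endothelial-like cells, differences of -32.7 and -35.7 percentage points with the same smallest exact permutation p. Il18 was present in 4.66% and Slpi in 3.08% of macrophage-like cells. The share was 99.8% in mesothelial-like and 41.2% in enteric neuron-like cells. Vascular endothelial-like cells express Fmo2 and Ntf3 themselves. Fibroblast-like cells as background gave -15.4 and -18.4 percentage points but held Aebp1, a list gene, in 19.1% of cells, so neither background tests for these transcripts. Without thinning the shares were 34.3% and 57.0%, against 70.7%. Median depths were 5123.5 UMIs in macrophage-like, 8625 in monocyte-like and 3321 in vascular endothelial-like cells, of which 1461, 1 and 319 cells lay below 1000 UMIs and were left out.

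Sex is the label that separates the mice, and the sex-linked genes matched it in all 4. Xist, the X-inactivation transcript (chromosome X, 103460366 to 103483254), was at 710 CPM in all cells of females summed and 0.132 CPM in males, a log2 difference, male minus female, of -12.34 ± 0.32 (edgeR adjusted p 0.00206, 2 mice per sex). The Y-linked Ddx3y was at 67.5 CPM in males and 0.0874 CPM in females (9.56 ± 0.23). Eif2s3y had 53.1 CPM in males and 0 counts in both females, at least 2225-fold higher against a floor of 3 counts over the females. Uty and Kdm5d had 2 counts each over both females, ratios of 3089 (95% counting interval 855 to 25508) and 1108 (307 to 9146). Tsix, which overlaps Xist and shares its reads unless strand was used in counting, was lower in males by -6.31 ± 0.26. Kdm6a (-0.86 ± 0.15), Kdm5c (-0.69), Eif2s3x (-0.64) and Ddx3x (-0.47), which escape X inactivation, were lower in males and did not pass. These 6 genes were all that edgeR called of 18856 tested, so 0 genes beyond the sex-linked list were called, with 1371 genes at an unadjusted p under 0.05, whereas DESeq2 called 163 genes, 156 beyond that list. Without female replicate 1, edgeR called 0 genes.

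**Figure D5:**
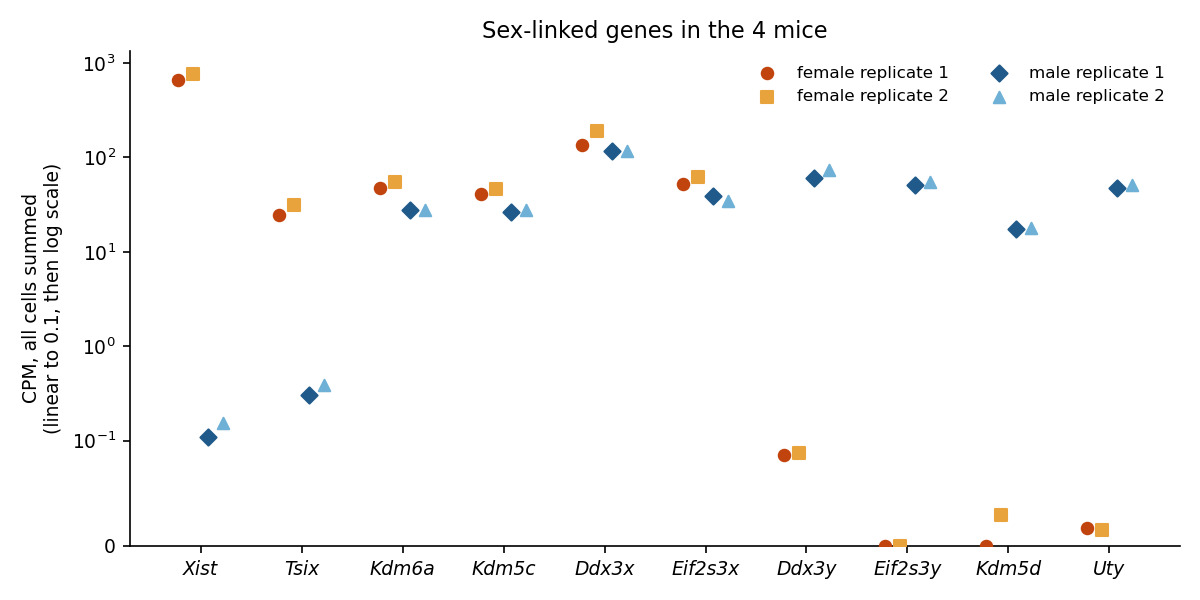
CPM of the 10 sex-linked genes in all cells summed, on an axis that is linear up to 0.1 and logarithmic above, with a point per mouse for 2 males and 2 females. Xist is at 710 CPM in females and 0.132 CPM in males, and Ddx3y at 67.5 CPM in males and 0.0874 CPM in females.

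Within classes, mesothelial-like cells had the most sex differences, 16 genes by edgeR, 9 of them beyond the sex-linked list. Il4ra, a receptor chain for interleukins 4 and 13, was lower in males by -1.22 ± 0.13 (15.3 against 36.5 CPM, 2 mice per sex), Bmp2 by -1.56 ± 0.22 (10.2 against 30.2 CPM), Prag1 by -1.58 and Gkn1 by -4.14 (0.241 against 4.95 CPM). Clec3b, the tetranectin gene, was higher in males by 1.64 ± 0.22 (95.4 against 31.2 CPM), with Rbfox1 (50.5 against 24.7 CPM), Bbox1 (0.99) and Zfp385a (0.97). In smooth muscle-like cells 8 genes passed, 2 beyond the list, both higher in males: Slpi by 2.14 ± 0.34 (6.03 CPM in females) and Dkk2, a Wnt antagonist, by 1.26 (71.6 against 30.6 CPM). With the stricter cell filter 0 genes beyond the list were called there. Slpi UMIs, most abundant in mesothelial-like cells, were also more frequent in fibroblast-like cells of males (5.76% and 3.88% of thinned cells) than of females (2.39% and 0.497%), so the Slpi value was not read as expression by smooth muscle. In lymphatic endothelial-like cells 8 passed, 6 beyond the list, all lower in males: Cd74 (-5.03 ± 0.86), H2-Eb1 (-5.49), H2-Aa (-4.78), Lyz2 (-4.13), Spp1 (-3.31) and Vtn, at 94.6 CPM in females and 1 count in the males (ratio 46.6, interval 8.36 to 1841), genes of antigen-presenting and other cells in a class with 16 cells in female replicate 2 and 13 in male replicate 1. DESeq2 kept Spp1 alone of the 6. Cd74 was at 181 CPM in female replicate 1 and 2922 CPM in female replicate 2, and Lyz2 at 137 and 1489 CPM, whereas Spp1 was at 674 and 338 CPM. Enteric glia-like cells had Ccl5 lower in males (-2.49, 2.03 against 11.7 CPM, a call not made with doublets kept). Free RNA adds UMIs to all classes, so this low Ccl5 value was not read as expression by glia. Fibroblast-like cells had the haemoglobin gene Hba-a2 lower (-1.77, turning to 0.21 with doublets kept). Macrophage-like cells had Capn11 lower (8.70 CPM in females and 2 counts in males, ratio 97.6, interval 27.0 to 806). Each was 1 gene beyond the list out of 7 and chosen after its values were seen.

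Beyond the sex-linked list, edgeR called 0 genes in 7 classes. The genes at an unadjusted p under 0.05 numbered 157 in dendritic cell-like, 205 in enteric neuron-like, 121 in interstitial cell of Cajal-like, 87 in monocyte-like, 55 in pericyte-like, 266 in T cell-like and 486 in vascular endothelial-like cells, and DESeq2 called 1 gene beyond the list in enteric neuron-like, monocyte-like and vascular endothelial-like cells each and 0 in the others. None of the 100 list genes had a class difference that itself differed by sex in any of 7 classes by edgeR (0 to 4 genes per class at an unadjusted p under 0.05). Single mice moved the counts: without female replicate 1 edgeR called 742 genes in vascular endothelial-like, 417 in smooth muscle-like and 216 in macrophage-like cells, whose clusters in that mouse were mostly its own, and 11 in mesothelial-like cells, where DESeq2 called 50 genes over all mice.

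Gene lists showed lower antigen-presentation, cell-cycle and interferon genes in males, in medians that did not pass with an estimated correlation. Of 142 tests of a list in a class, camera with a preset correlation called 50, 40 lower and 10 higher in males, and 12 held without each mouse in turn. Medians are of camera's differences in mean log2 CPM with a small added count, while values of single genes and counts of lower genes come from edgeR's fits. In all cells the cell cycle list had a median log2 difference of -1.04 with 19 of 20 genes lower in males, such as Ccnb1 (-1.70 ± 0.60) and Ube2c (-1.45 ± 0.44), the chemokine receptors -0.77 with 17 of 20, and the MHC class II genes -0.83 with 10 of 10, such as H2-DMb2 (-1.89 ± 0.51) and H2-Oa (-1.72 ± 0.30). The all-cell sums also held fewer T cell-like (0.979 against 3.15%), dendritic cell-like (0.339 against 0.858%) and macrophage-like cells (32.3 against 38.3%) in males, so these medians do not separate expression from shares. MHC class II genes were lower in males also in fibroblast-like (-1.27, 7 of 7) and interstitial cell of Cajal-like cells (5 of 6, such as Cd74 by -1.60 ± 0.45), and higher in T cell-like cells (1.43). Interferon response genes were lower in vascular endothelial-like cells (-0.60, 22 of 23), with Rsad2 at 108 CPM in males and 207 CPM in females, and in smooth muscle-like cells (-0.43, 12 of 14), where chemokine ligands were lower too (-0.32, 8 of 10). Cell cycle genes were lower in macrophage-like (-0.61, 19 of 20) and fibroblast-like cells (-0.32, 10 of 12), and chemokine receptors in enteric glia-like cells (-0.22, 4 of 6). The MHC class II and chemokine genes were low in the non-myeloid classes where they were lower, such as H2-Aa in fibroblast-like cells (21.0 CPM in males, 7223 CPM in macrophage-like cells). Ccl8 in smooth muscle-like cells was at 4.72 CPM in males. With lower mean macrophage- and dendritic cell-like shares in males, and free RNA in all classes, these lower medians were not read as expression by those classes. T cell-like cells went the other way, with Cd74 at 1078 CPM in males and 395 CPM in females. Lower myeloid shares in males would not give that rise, whose cause was not tested. With an estimated correlation 0 of the 142 tests passed (adjusted p 0.945 for each), against 50 with the preset one in camera, and edgeR called 0 members in the class of its own test in these 12 tests.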

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

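All explanation tests below were on patterns found in these data, and the comparison of macrophage-like with T cell-like cells, the test of Il18 alone and the tests of Spp1 and Vtn as macrophage RNA, with their bounds, were chosen only after their results were seen. Of 28 values tested for a mouse far from the others, 2 stood out, and chance alone marks about 1 in 20. Ret in enteric neuron-like cells was at 162 CPM in male replicate 2 and between 199 and 204 CPM in the other mice, a gap that took a share of 0.877 of the range. Bmp2 in fibroblast-like cells was at 148 CPM in male replicate 1 and between 97.5 and 104 CPM in the others, a gap of 0.866 of the range.

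Cells in 10 clusters entered no comparison because the clusters stayed unnamed. Cluster 18 (496 cells), all from male replicate 2, was led by Igfbp6, Fabp4, Car3 and Hbb-bs with a median of 18.3% mitochondrial UMIs. Cluster 26 (208 cells) was led by Robo2, Kcnn3, Pdgfra and Cfd, cluster 31 (132 cells) by the immunoglobulin genes Igkc and Igha with Jchain, cluster 32 (123 cells) by Skap1, Inpp4b, Ctla2a and Ltb, and cluster 35 (33 cells), all from female replicate 1, by the pancreatic genes Ctrb1, Prss2, Clps and Try4. Retnla led 5 clusters: cluster 10 (157 cells), cluster 39 (137 cells), cluster 41 (112 cells), cluster 43 (69 cells) and cluster 44 (66 cells). Of these 541 cells 439 came from female replicate 2, or 4.53% of its cells against 0.578% in female replicate 1, 0.556% in male replicate 1 and 0.255% in male replicate 2. At resolution 2.0 a cluster of 699 cells led by Retnla, Ear2, Mmp12 and Mgl2, 566 from female replicate 2, took the macrophage-like name. The main macrophage-like share and comparisons leave the 5 Retnla clusters out.

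Pancreatic acinar genes were abundant in female replicate 1 outside cluster 35. A list of 23 such genes, drawn after that cluster was seen, held 1273 CPM and 8.68 UMIs per cell there, with a UMI in 99.0% of cells, against 4.63%, 8.02% and 6.45% of cells in female replicate 2 and male replicates 1 and 2 (8.24, 28.5 and 17.5 CPM). Ctrb1 was at 239 CPM and Prss2 at 115 CPM in female replicate 1. In cluster 35 the list took 65.6% of UMIs. If macrophages had taken up the RNA they would hold the most, but their mean per cell was 0.814 of the highest other class, which argues against that. Free RNA in the suspension stays open as a candidate source: the list's gene proportions in each class correlated with those in cluster 35, with a lowest Pearson r across genes of 0.905 (pericyte-like cells), and genes are not independent replicates. This RNA may also have set apart macrophage clusters of that mouse. When macrophage-like cells were clustered again without the list, 0 percent of its cells lay in clusters made almost wholly of it, but only 24.8% did with all variable genes, so that test could hardly have failed. This RNA was in 1 mouse, so no difference between the sexes was tested.

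Mesoderm-derived list UMIs in macrophage-like cells lay below the vascular endothelial-like background. Without Il18 the difference was -37.19 percentage points, and leaving Il18 out moved the mean difference by 13.71 percent of its size in a test void for macrophage-like cells below background, and this background expresses list genes itself, so these 2 values decide nothing. Against T cell-like cells the difference without Il18 was -0.261 percentage points, as free RNA would give. For Il18 alone, a UMI was present in 4.66% ± 0.489 of macrophage-like cells, against 0.0958% of vascular endothelial-like and 0% of T cell-like cells. The difference from vascular endothelial-like cells was 4.56 percentage points, above 0 in 4 of 4 mice, which argues against free mesothelial-like RNA as the whole cause of the Il18 UMIs.

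The 6 myeloid and other genes were lower in males in lymphatic endothelial-like sums. RNA or cells of macrophages in the sum of female replicate 2 may account for its Cd74, H2-Aa, H2-Eb1 and Lyz2. The median log2 difference of 14 macrophage markers outside the called genes was -2.71. Their median CPM was 9.68 and 243 in female replicates 1 and 2, and 0 and 9.40 in male replicates 1 and 2. Female replicate 1 was thus close to male replicate 2 in that median, while its Cd74 was higher (181 against 51.7 CPM), so its values stay open. The excess of these markers lay mainly in the 16 cells of female replicate 2. Apoe was at 523 and 4378 CPM in female replicates 1 and 2 and 89.3 and 510 CPM in male replicates 1 and 2, and C1qb at 65.0 and 903 against 14.9 and 23.5 CPM. Macrophages as the source of Spp1 and Vtn are argued against, since macrophage-like sums of the females held at most 0.0301 and 0.00834 of the CPM of the lymphatic endothelial-like sums. For these 2 genes only macrophage-like sums were compared, so other classes were not tested as their source. Vtn is 1 of the pericyte markers and led the pericyte-like cluster 24, and Spp1 was higher in monocyte-like than in macrophage-like cells. Spp1 was higher in female replicate 1 (674 CPM) than in female replicate 2 (338 CPM). For dendritic cells only 2 markers had counts, which was too few. A difference between the sexes in lymphatic endothelial cells themselves stays open and untested.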

How the results depend on the processing

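With 2 mice per sex, the sex comparisons recovered few simulated changes under 4-fold, and the calls of genes with few counts depended on the test. Few-marker monocytes left out, single-mouse macrophages left out and no thinning were chosen after seeing the data. No paired analysis was possible because the replicate numbers of males and females pair nothing. Of 516 values of counts, shares and differences under the alternatives, 349 stayed close, 165 moved and 2 reversed. A count stayed close within a ratio of 1.5, and a share if its mean moved by less than the SD over mice. A difference from background counted as close if its sign held, whatever its size. Leaving out a mouse cannot move a mean share by its SD, so those share values were bound to stay close. Of the genes named for a class, 1069 values kept their call and 1 weakened (Ccl2 in fibroblast-like cells with DESeq2). Of those named for sex, 248 kept it, 40 weakened, 1 strengthened and 1 reversed, and for monocyte-like against macrophage-like cells 429 kept it, 35 weakened and 4 reversed. Only the 12 list tests that held without each mouse were counted here, so their 48 values without a mouse kept the call by selection. The other called list tests did not hold without each mouse. With the estimated correlation all 12 weakened. The cause was not tested for the results below.

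Without the replicate block, list genes higher numbered 41 in macrophage-like, 40 in monocyte-like, 35 in mesothelial-like, 28 in enteric glia-like, 23 in enteric neuron-like, 41 in fibroblast-like and 20 in smooth muscle-like cells, and 34 genes differed between monocyte-like and macrophage-like cells.

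The counts below are genes called between the sexes, with those beyond the sex-linked list in parentheses. DESeq2 gave 163 (156) in all cells, 13 (7) in fibroblast-like, 2 (1) in lymphatic endothelial-like, 20 (13) in macrophage-like, 50 (40) in mesothelial-like and 5 (1) in monocyte-like cells, and beyond the list 3 in enteric glia-like, 1 in enteric neuron-like and 1 in vascular endothelial-like cells. With no filter on low counts there were 10 (4) in all cells, 33 (29) in dendritic cell-like, 92 (86) in enteric glia-like, 57 (52) in enteric neuron-like, 118 (111) in fibroblast-like, 52 (46) in interstitial cell of Cajal-like, 38 (34) in lymphatic endothelial-like, 234 (227) in macrophage-like, 326 (316) in mesothelial-like, 41 (36) in monocyte-like, 20 (15) in pericyte-like, 83 (76) in smooth muscle-like, 60 (54) in T cell-like and 335 (326) in vascular endothelial-like cells. RLE size factors gave 5 (1) in dendritic cell-like and 12 (10) in lymphatic endothelial-like cells. With doublets kept there were 6 (2) in dendritic cell-like, 5 (4) in pericyte-like and 7 (2) in T cell-like cells, and beyond the list 0 in enteric glia-like, 0 in fibroblast-like, 2 in macrophage-like and 1 in smooth muscle-like cells, and Hba-a2 turned to 0.21. Resolution 2.0 gave 5 (1) in dendritic cell-like and 1 beyond the list in T cell-like cells. The stricter cell filter gave 16 (13) in lymphatic endothelial-like and 3 (2) in pericyte-like cells, and beyond the list 2 in enteric glia-like, 1 in enteric neuron-like and 0 in smooth muscle-like cells. With single-mouse macrophages left out, 3 genes beyond the list were called in macrophage-like cells, whose share was 29.6%.

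Without each mouse in turn, the counts ranged from 0 to 17 (0 to 12) in all cells, 0 to 30 (0 to 28) in dendritic cell-like, 9 to 115 (3 to 109) in enteric glia-like, 2 to 66 (1 to 62) in enteric neuron-like, 6 to 135 (0 to 129) in fibroblast-like, 0 to 34 (0 to 28) in interstitial cell of Cajal-like, 15 to 45 (14 to 44) in lymphatic endothelial-like, 8 to 216 (2 to 209) in macrophage-like, 11 to 198 (6 to 189) in mesothelial-like, 1 to 23 (0 to 22) in monocyte-like, 8 to 45 (7 to 43) in pericyte-like, 42 to 417 (36 to 407) in smooth muscle-like, 10 to 36 (6 to 32) in T cell-like and 0 to 742 (0 to 733) in vascular endothelial-like cells. The number of list tests called ranged from 27 to 66. Between monocyte-like and macrophage-like cells Ccr7 ranged from -1.61 to 6.29, Csf1 from -0.44 to 1.60 and Cxcl9 from -0.073 to 3.24.

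With the estimated correlation 0 list tests passed, against 50 with the preset one. With fibroblast-like cells as background the enteric neuron marker differences were 10.5 and 2.75 percentage points for macrophage-like and monocyte-like cells. With few-marker monocytes left out Ccl24 turned to -0.26. With no filter 51 list genes differed between monocyte-like and macrophage-like cells, against 36. Genes lower in a class numbered 36 with DESeq2 against 12 in macrophage-like, 25 against 15 in monocyte-like, 46 against 21 in mesothelial-like, 36 against 16 in enteric glia-like, 32 against 14 in fibroblast-like and 49 against 23 in smooth muscle-like cells. Doublets kept gave 25 against 11 lower genes in enteric neuron-like cells. Without female replicate 2 it was 10 against 16 in enteric glia-like, 8 against 14 in fibroblast-like, 7 against 12 in macrophage-like, 13 against 21 in mesothelial-like and 15 against 23 in smooth muscle-like cells.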

Other observations

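The counts over other splits of the samples were planned, and the macrophage-like cluster values were chosen after the data were seen. Class names were shuffled within each mouse in 24 splits, the real one included, and in each of the 7 classes 1 split, the real one, gave as many list genes higher. The classes came from clustering the same cells, so shuffled names were bound to give fewer genes, and these splits were not used to exclude chance. The real count and the highest of the other splits were 42 and 22 for macrophage-like, 40 and 11 for monocyte-like, 34 and 10 for mesothelial-like, 29 and 12 for enteric glia-like, 24 and 10 for enteric neuron-like, 39 and 10 for fibroblast-like, and 20 and 13 for smooth muscle-like cells. For monocyte-like against macrophage-like cells, 1 of 35 splits gave as many changed genes, with 36 in the real split and 15 in the highest other, and the same limit applies.

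Clusters 0, 2, 9 and 21, the macrophage-like clusters with at least 40 cells in each mouse and a median of at least 4000 UMIs, differed in the chemokine and neurotrophic genes that had been kept out of the clustering. In cluster 9 (1029 cells), led by F13a1, Folr2 and Lyve1, Ccl8 was at 4950 ± 1813 CPM against 557 CPM in the other clusters, Ednrb at 114 ± 29.8 against 3.84 CPM, Ccl24 at 132 against 20.2 CPM and Gas6 at 663 against 226 CPM, whereas Cx3cr1 was at 281 against 1020 CPM and Ccr2 at 32.1 against 414 CPM (n = 4 mice). In cluster 2 (2639 cells), led by C1qa and MHC class II genes, Ccr2 was at 766 ± 90.7 against 169 CPM and Il1b at 58.2 against 8.75 CPM, and Ccl8 was at 209 against 2137 CPM. Each of these differences had the same direction in 4 of 4 mice.

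Some abundant transcripts differed between mice of the same sex. Gm42418 was at 38919 CPM in male replicate 1 and 18292 CPM in male replicate 2, and at 16942 CPM in female replicate 1 and 37196 CPM in female replicate 2. Hbb-bs was at 648 CPM in female replicate 1, against 186 CPM in female replicate 2, 209 CPM in male replicate 1 and 85.5 CPM in male replicate 2.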
